A study of Caenorhabditis elegans with 9 samples.

How the data were processed

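RNA of *C. elegans* grown at 3 hemin concentrations was measured on 9 Affymetrix whole genome arrays, 3 per concentration. The deposited table held 1 log2 expression value per probe set and array, already normalized between arrays by the authors, and the submitters' processing notes name MAS5 and RMA, without versions. All values lay between 2.02 and 14.37 with nearly equal quartiles on every array, which is the form of RMA values and not of linear MAS5 signals. The lower quartile and median were 3.90 and 5.57 on 4 uM replicate A, against 3.70 to 3.77 and 5.43 to 5.47 on the others. Which of these methods made the table, and with what settings, is not given in the sources used here. Background correction and summarisation of probes by the authors can compress differences among dim probe sets, and a single normalization over all arrays ties each array's values to the others. Detection calls, scanner files and scan dates were not used here, so no level above background could be set and no scan batch could be examined.

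Groups and replicate letters were taken from the labels, which name 3 biological replicates per concentration. No value column other than those of the 9 arrays was used. Of 22625 probe sets 77 were array controls and were left out of the tests. Gene names came from the platform's annotation: 20766 probe sets carried 1 gene symbol, 887 several and 895 none, and a probe set with several symbols was not named. By Entrez identifier 20701 of those with 1 symbol matched a table of current genes (assembly WBcel235, used for names only), and 0 symbols changed. Between any pair of arrays 244 to 1081 values were identical, at a median of 4.32 in the pair with the most, so no array was a copy of another.

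The dimmest 25% of the gene probe sets by mean over all arrays were left out, which left 16911. A linear model with 1 mean per concentration was fitted over all 9 arrays with limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom and moderated variances that follow the mean level. The contrasts were 4 minus 20, 500 minus 20 and 500 minus 4 uM hemin, beside a moderated F-test over the 3 groups. All limma p-values were two-sided and adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05, and errors of differences are standard errors from limma's moderated variances on the log2 scale unless given as SD.

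Named genes were, per contrast, the 10 largest rises and 10 largest falls among called probe sets with 1 gene symbol whose groups did not overlap, all measured members of the heme transport and iron homeostasis lists, and up to 4 members of each other list with the smallest p. The probe set with the highest mean stood for a gene with several. The main tests, lists, this rule and the alternatives were fixed before the data were examined, and some tests of explanations were chosen after, as said beside them. The 36 gene lists were tested with camera at a preset correlation of 0.01, adjusted over 108 tests, beside camera with an estimated correlation and fry. In 16 of the 108 list tests the median, the mean and the direction of the test differed in sign, and 0 of these were called.

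Overlap between the contrasts that share the 20 uM arrays was set against 100 simulations of unchanged groups, with lists of equal length taken by rank. The alternatives were quantile normalization, centring of each array, other filters on dim probe sets, other variance priors, the replicate letter as a block, array weights, fits of the 6 arrays of a contrast, a fold threshold, other rules for several probe sets per gene, and leaving out each array in turn. The limma step was tested on simulated data over 16911 probe sets with 50 changed per size. A log2 change of 1 was recovered in 98%, 90% and 94% of cases for 4 minus 20, 500 minus 20 and 500 minus 4, and one of 0.5 in 32%, 30% and 38%. Of the calls made there 5.7%, 7% and 4% were false. The simulated noise had 1 SD per probe set on all arrays, with no array apart and no correlation between genes. Recovery and false calls in the real data may therefore differ. Tables were handled with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.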

Results

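Gene expression was measured in *Caenorhabditis elegans*, a nematode that does not synthesise heme and takes it up from its surroundings. Worms were kept without bacteria in the liquid medium mCeHR-2, to which hemin, the chloride of iron(III) protoporphyrin, was added at 4, 20 or 500 uM, and RNA was taken at the late L4 larval stage. Each concentration was represented by 3 biological replicates, named A, B and C, with 1 Affymetrix whole genome array each, which gave 9 arrays in all. The table held log2 values of 22625 probe sets, between 2.02 and 14.37. The number of arrays limited the precision: the median standard error of a log2 fold change between groups was 0.12.

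Among the 9 arrays, 4 uM replicate A stood apart. Its Spearman correlations with the other 8 arrays were 0.973 to 0.985 across probe sets, and the lowest correlation among those 8 was 0.990. The SD of its deviations from the other 2 arrays of its group was 0.43, against 0.15 to 0.31 for the remaining arrays. The first principal component took 45.9% of the variance, with this array at one end.

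**Figure D1:**
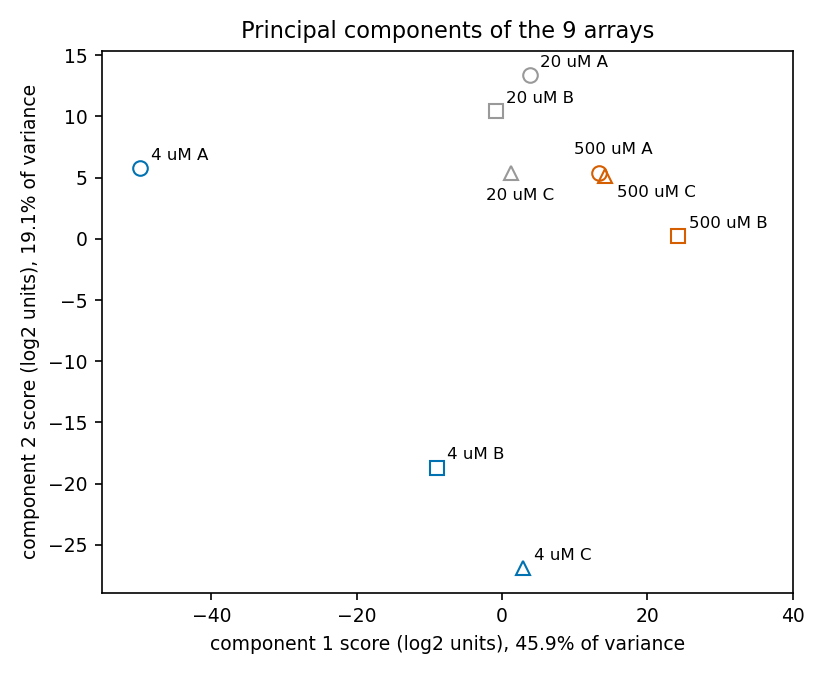
Scores of the 9 arrays on the first 2 principal components of the log2 values (axes in log2 units, 45.9% and 19.1% of the variance); each point is 1 array, coloured by hemin concentration and shaped by replicate letter. The array of 4 uM replicate A lies at a component 1 score of -49.77, and the other 8 lie between -9.02 and 24.26.

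The comparison of 4 with 20 uM hemin asked which transcripts respond to a low heme supply. Of 7 heme transport genes 4 rose at 4 uM hemin. The transcript of *hrg-3* (F58E6.7), which encodes a secreted heme-binding protein, went from 2.37 ± 0.09 to 8.03 ± 0.82 (log2, mean ± SD, n = 3 arrays each), a rise of 5.66 (SE 0.31, adjusted p = 1.41e-05). On the 20 and 500 uM arrays *hrg-3* read 2.27 to 2.58, near the lowest value of the table. Without detection calls its level there is only a bound, and its differences from 4 uM are lower bounds. The heme transporter gene *hrg-1* (R02E12.6) rose by 3.97 (SE 0.11, adjusted p = 1.99e-07), or 15.7-fold. A similar rise of 4.01 (SE 0.14, adjusted p = 6.05e-07) was found for *hrg-7* (C15C8.3), whose product resembles aspartic proteases. The ABC transporter gene *mrp-5* (F14F4.3), known for heme export from the intestine, rose by 1.59 (SE 0.12, adjusted p = 0.000133), and its second probe set by 1.76.

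In this list 7 members rose when adjusted over the list alone. The study chose the hrg genes on these samples, so their count is not independent evidence of a direction. The list had a median log2 fold change of 2.46 and a camera adjusted p of 4.85e-21, with adjusted p = 0.0615 with an estimated correlation. The paralogous transporter gene *hrg-4* (F36H1.5) differed by 2.46 (SE 0.60, adjusted p = 0.144) and *hrg-9* by 0.70 (adjusted p = 0.199). On 4 uM replicate A *hrg-4* read 6.35, against 8.89 and 9.33 on replicates B and C. Without that array *hrg-4* rose by 3.38 (SE 0.15, adjusted p = 2.83e-06) and *hrg-9* by 0.96 (SE 0.10, adjusted p = 0.000788). The remaining member, *hrg-10*, differed by 0.24 (adjusted p = 0.52).

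**Figure D2:**
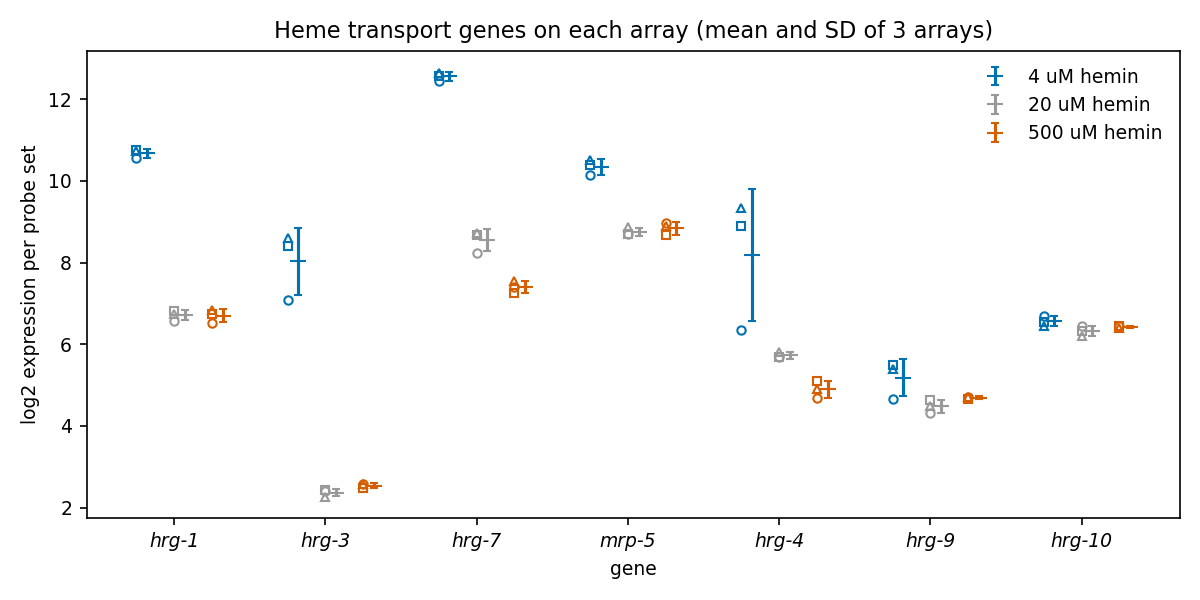
Log2 expression of 7 heme transport genes (y axis, log2 units) at 4, 20 and 500 uM hemin; open symbols are single arrays (circle, square and triangle for replicates A, B and C), and bars are the mean and SD of 3 arrays. At 4 uM hemin *hrg-3* averages 8.03, against 2.37 at 20 uM and 2.54 at 500 uM.

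Of 9 tested genes of iron homeostasis, 1 rose, 1 fell and 7 did not pass. The ferroportin gene *fpn-1.2* fell by 1.03 (SE 0.10, adjusted p = 0.000849). The ferritin gene *ftn-1* rose by 1.66 (SE 0.32, adjusted p = 0.0494), and that call was lost without 1 of 7 arrays (4 uM replicate B or any array of 20 or 500 uM), with adjusted p up to 0.229. It was also lost under quantile normalization, centring, no filter, both other variance priors, the replicate block and the fit of 6 arrays (up to 0.20). Adjusted over the list alone, 2 members rose and 1 fell.

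Outside these lists, *gsto-1*, an omega-class glutathione transferase gene, rose by 3.57 (SE 0.18, adjusted p = 9.39e-06). The cathepsin B-like gene *cpr-8* rose by 2.58 (SE 0.13) and *ctsa-4.1*, of the cathepsin A-like carboxypeptidases, by 2.84 (SE 0.19), whereas the lysosomal lipase gene *lipl-2* fell by 1.44 (SE 0.15) and the acid sphingomyelinase gene *asm-3* fell by 2.57 (SE 0.27). The gene *pud-3* fell by 3.56 (SE 0.18), and *pud-4* fell by 3.43 (SE 0.26). Among 130 tested C-type lectins 4 rose and 1 fell (13 and 8 adjusted over the list alone): *clec-45* rose by 3.51 (SE 0.36) and *clec-52* fell by 3.25 (SE 0.33). Of 40 tested glutathione transferases 2 rose, also adjusted over the list alone. The call of 1 of them, *gst-6*, was lost without any array but 4 uM A (up to 0.244), and under quantile normalization, centring, no filter, the replicate block and the fit of 6 arrays. Of 53 UDP-glucuronosyltransferases 4 rose and 2 fell (11 and 4 adjusted over the list alone), and *ugt-17* rose by 1.84 (SE 0.14). Without 4 uM A, 9 lectins rose and 6 fell, and 12 UDP-glucuronosyltransferases rose and 3 fell. Adjusted p lay between 9.39e-06 and 0.00131 for the genes of this paragraph whose changes are given.

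In the oocyte and embryo list, 7 of 26 members rose at 4 uM hemin, 18 when adjusted over the list alone, and all 26 fold changes were positive (median 0.56). The eggshell gene *perm-2* rose by 1.72 (SE 0.16, adjusted p = 0.000769), the RNA-binding protein gene *pos-1* by 0.95 (SE 0.10, adjusted p = 0.00136) and *puf-5*, of the Pumilio family, by 0.75 (SE 0.10, adjusted p = 0.00627). Camera gave adjusted p = 2.42e-23 for this list, and adjusted p = 0.166 with an estimated correlation. Of 5 measured yolk protein genes 2 rose, 5 when adjusted over the list alone (median 1.93, camera adjusted p = 1.92e-08, adjusted p = 0.225 with an estimated correlation). The yolk genes *vit-2* (2.62, SE 0.44, adjusted p = 0.0252) and *vit-1* (0.59, SE 0.11, adjusted p = 0.0454) were these. The call of *vit-2* was lost without 4 uM B, 4 uM C, 20 uM A, 20 uM B or 500 uM B (adjusted p up to 0.150), and that of *vit-1* without any array but 4 uM A (up to 0.174). The *vit-1* call was also lost under quantile normalization, centring, no filter, the replicate block and the fit of 6 arrays (up to 0.151). Of 40 tested major sperm protein genes 0 passed in limma over all probe sets, 32 had an unadjusted p under 0.05 and 28 passed adjusted over the list alone. Their median was 0.72 with 40 of 40 positive (camera adjusted p = 3.36e-20, adjusted p = 0.382 with an estimated correlation). By its symbol rule the list of major sperm protein genes took msp, msd, ssp, nspd and ssq genes. The msp genes among them are near-identical copies, so their probe sets can share signal. Against the other 2 arrays of its group, 4 uM replicate C deviated by -0.87 in the median of the sperm list, by -0.23 in the oocyte list and by 0.29 in the yolk list. These deviations were 0.98, 0.26 and -0.88 on 4 uM replicate A. Without it the medians of the differences were 0.43, 0.42 and 2.21, and all 5 yolk genes rose. The 30 genes of germline proliferation and meiosis had a median of 0.05 with 0 passed and no camera call (adjusted p = 0.308).

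Cuticle collagens rose in 7 of 141 cases (18 adjusted over the list alone, 1 lower; median 0.17, camera adjusted p = 1.75e-09, adjusted p = 0.362 with an estimated correlation). The adult collagen gene *col-19* rose by 2.28 (SE 0.32, adjusted p = 0.00874, lost at 0.0570 without 20 uM B). The 25 histone genes had a median of 0.15 with 0 passed in limma, 6 at an unadjusted p under 0.05 and 5 adjusted over the list alone (camera adjusted p = 0.000285, adjusted p = 0.362 with an estimated correlation). On 4 uM replicate A the collagen median deviated by 0.27, and without that array the collagen median was 0.09 and 13 collagens rose and 1 fell.

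Other lists shifted down by small amounts at 4 uM hemin. Fatty acid metabolism had a median of -0.10 with 2 of 36 members lower, of which *lipl-1* fell by 1.47 (SE 0.20, adjusted p = 0.00787, lost at 0.0573 without 20 uM A and at 0.0591 in the fit of 6 arrays) and the 3-hydroxyacyl-CoA dehydrogenase gene *hacd-1* fell by 0.81 (SE 0.13, adjusted p = 0.0188). The *hacd-1* call was lost without 4 uM B, 4 uM C or any 20 uM array (up to 0.0936) and in the fit of 6 arrays (0.0708). Adjusted over the list alone, 3 were lower. Camera gave adjusted p = 2.77e-06 for it, and adjusted p = 0.109 with an estimated correlation. Endoplasmic reticulum stress genes (median -0.15, camera adjusted p = 6.06e-06, adjusted p = 0.166 with an estimated correlation) and short-chain dehydrogenases (median -0.08, camera adjusted p = 0.00445, adjusted p = 0.382 with an estimated correlation) followed. These lists held 0 members passed of 19 and 30 in limma, 6 and 9 at an unadjusted p under 0.05, and 1 and 4 lower adjusted over the list alone. Cytosolic heat shock genes (median -0.26, camera adjusted p = 0.0371), the lysozyme and defence list (-0.04, 0.0492) and molting genes (-0.08, 0.0492) passed camera narrowly, with adjusted p = 0.263, 0.263 and 0.503 with an estimated correlation. The lysozyme and defence list held lysozymes, saposins, antimicrobial peptides and, by its symbol rule, irg and dod genes. Of its 58 members 2 fell, *spp-8* and *dod-3*, and 9 were lower and 1 higher adjusted over the list alone. The *spp-8* call was lost with the replicate block (limma adjusted p = 0.0660) and in the fit of 6 arrays (0.110). Its other probe set differed by -0.33 without a call. Of 8 heat shock and 27 molting genes 0 passed in limma, 2 and 8 had an unadjusted p under 0.05, and adjusted over the list alone 0 heat shock genes passed and 6 molting genes were lower and 1 higher. Without 4 uM A, 10 of the lysozyme list fell and 2 rose, with a median of -0.01. Of the molting genes 2 fell, with a median of -0.29 (camera adjusted p = 0.00468). Without 1 array the lysozyme median ran from -0.09 (4 uM B) to 0.01 (20 uM A), across 0. The molting median was -0.01 without 4 uM C. The median of short-chain dehydrogenases was -0.15 without 4 uM A and -0.03 without 4 uM C. That of the stress genes was -0.10 without 4 uM C and that of fatty acid metabolism -0.15 without 20 uM A. The heat shock, lysozyme and molting calls were lost under quantile normalization. The heat shock call was lost without 4 uM A, 4 uM C or 20 uM C (up to 0.137). That of the lysozyme list was lost without a filter, with the mean of all probe sets of a gene, and without 4 uM A, 4 uM C, 20 uM C or any 500 uM array (up to 0.242), and that of the molting list without 4 uM B, 4 uM C, 20 uM B, 20 uM C or any 500 uM array (up to 0.20).

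The 6 targets of the hypoxia factor HIF-1 had a median of -0.35 at 4 against 20 uM hemin with 0 passed in limma, 2 at an unadjusted p under 0.05, 0 adjusted over the list alone and no camera call (adjusted p = 0.0656). On 4 uM replicate A their median deviated by 0.82. Without that array it was -0.65, 3 targets fell and camera gave adjusted p = 0.000377. Without it camera also called UDP-glucuronosyltransferases (adjusted p = 0.00055), intestine markers (0.00943), copper and iron-sulfur proteins (0.0315) and glutathione transferases (0.0386), all with positive medians.

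The counts of list members that passed at 4 against 20 uM hemin moved with the arrays. Over the 9 fits that left out 1 array 0 to 13 collagens, 4 to 9 oocyte genes and 0 to 5 yolk genes rose. In these fits 2 to 9 lectins rose and 1 to 6 fell, and 1 to 12 UDP-glucuronosyltransferases rose and 0 to 3 fell. Of fatty acid metabolism 0 to 3 genes fell, and of the lysozyme and defence list 1 to 10. In the fit of 6 arrays 1 collagen, 4 oocyte genes and 1 UDP-glucuronosyltransferase rose, and 5 lectins and 0 genes of fatty acid metabolism fell.

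In all, 154 of 16911 probe sets differed between 4 and 20 uM hemin by limma at an adjusted p under 0.05, 115 higher and 39 lower, standing for 134 named genes. The count was 315 without 4 uM replicate A, 92 without 4 uM B, 69 without 20 uM A and 78 without 20 uM B, 86 when only the 6 arrays of these groups entered the fit and 899 with array weights. Of the 20 genes named for the size of change, 13 kept their call in all 9 fits that left out 1 array, *hrg-3*, *hrg-7*, *hrg-1*, *gsto-1*, *pud-3* and *pud-4* among them. The rule for those 20 required every array of one group to lie above every array of the other, a separation that chance gives to 10% of unchanged genes.

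The comparison of 500 with 20 uM hemin asked which transcripts respond to an excess. In the main fit 41 probe sets were called, against 154 at 4 uM. This order reversed in fits of only the 6 arrays of a contrast, with 203 against 86. Of the 4 heme transport genes that rose at 4 uM hemin, *hrg-7* alone passed. The infection response gene *irg-4* rose by 1.95 (SE 0.21, n = 3 arrays per group, adjusted p = 0.00695), *dod-19*, a gene known to lie downstream of DAF-16, by 1.26 (SE 0.13, adjusted p = 0.00695) and F49F1.5 by 1.47 (SE 0.11, adjusted p = 0.00152). At 500 uM hemin Y105C5B.7 fell by 2.90 (SE 0.25, adjusted p = 0.00231), *pud-3* fell by 2.01 (SE 0.18, adjusted p = 0.00251), and the C-type lectin gene *clec-47* fell by 3.24 (SE 0.48, adjusted p = 0.0281). The *clec-47* call was lost without 4 uM B, any 20 uM array or 500 uM B (adjusted p up to 0.164), and the *irg-4* call without 20 uM A (0.0512). The calls of *dod-19*, F49F1.5, Y105C5B.7 and *pud-3* stayed in all 9 such fits.

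In the heme transport list 1 of 7 members fell and 6 did not pass, and the same count was obtained adjusted over the list alone, for a list the study chose on these samples. The gene *hrg-7* fell by 1.14 (SE 0.14, adjusted p = 0.0115), with the call lost without 20 uM B, 20 uM C, 500 uM A or 500 uM B (up to 0.0785). The differences were -0.01 (SE 0.11) for *hrg-1* and 0.09 (SE 0.12) for *mrp-5*, and *hrg-3* lay near the lowest values in both groups. The difference was -0.83 (SE 0.60, adjusted p = 0.898) for *hrg-4*, which without 4 uM A had SE 0.13 and adjusted p = 0.0212. The list's median was 0.09 and its mean -0.20, of opposite sign. Of 9 iron homeostasis genes 0 passed in limma, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone.

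Among lectins 3 of 130 rose (*clec-17*, *clec-65* and *clec-143*) and 1 fell, with 21 higher and 4 lower adjusted over the list alone (median 0.07, or 0.04 without 500 uM C, camera adjusted p = 1.86e-05, adjusted p = 0.316 with an estimated correlation). The gene *clec-17* rose by 1.52 (SE 0.16, adjusted p = 0.00695, lost at 0.0533 without 500 uM B). The call of *clec-65* was lost without 4 uM B, any 20 uM array, 500 uM A or 500 uM B (up to 0.139), and that of *clec-143* without any array but 4 uM A (up to 0.226). Both were lost with the replicate block (0.0826 and 0.0917), and *clec-143* also under quantile normalization, centring and no filter. The other probe set of *clec-65* differed by 0.76 without a call. Of the 58 members of the lysozyme and defence list 3 rose, *irg-4*, *dod-19* and the saposin-like gene *spp-18*, and 0 of these are lysozymes. In it 6 were higher and 2 lower adjusted over the list alone, without a camera call. The *spp-18* call was lost without any 20 uM array, 500 uM A or 500 uM B (up to 0.123). Of 40 glutathione transferases 1 fell: *gst-19* fell by 1.18 (SE 0.14, adjusted p = 0.0090, lost without 20 uM B or 500 uM B at up to 0.0579), although the list's median was 0.11 (camera adjusted p = 0.00542, adjusted p = 0.225 with an estimated correlation) and 4 were higher and 2 lower adjusted over the list alone.

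Camera called 3 reproductive lists lower at 500 against 20 uM hemin, with no member past the threshold over all probe sets. It did not call germline proliferation and meiosis (median -0.04, 0 of 30 passed, camera adjusted p = 0.146). The 40 major sperm protein genes were all negative (median -0.65, camera adjusted p = 2.60e-22, adjusted p = 0.362 with an estimated correlation), with 0 passed in limma, 22 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The 26 oocyte and embryo genes (median -0.11, camera adjusted p = 0.000899, adjusted p = 0.551 with an estimated correlation) had 0 in limma, 0 unadjusted and 0 adjusted over the list alone. The 5 yolk genes (median -0.53, camera adjusted p = 0.00174, adjusted p = 0.411 with an estimated correlation) had 0 in limma, 1 unadjusted and 1 lower adjusted over the list alone, and this list's call was lost without 20 uM C or 500 uM A (up to 0.105). Collagens (median -0.04, camera adjusted p = 0.00138, adjusted p = 0.590 with an estimated correlation; lost without 20 uM C or 500 uM B at up to 0.175) and molting genes (median -0.26, camera adjusted p = 0.000266, adjusted p = 0.263 with an estimated correlation) were lower too, with 0 members of 141 and 27 passed in limma, 11 and 8 unadjusted, and 0 adjusted over the list alone. Without 1 array these medians ran from -0.79 (500 uM C) to -0.16 (500 uM A) for yolk genes. They ran from -0.18 (500 uM C) to -0.05 (500 uM B) for oocyte genes and from -0.08 (500 uM C) to -0.02 (20 uM C) for collagens. The molting median was -0.17 without 500 uM B.

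The 6 HIF-1 targets had a median of -0.53 at 500 against 20 uM hemin and were all negative, with 0 passed in limma, 4 at an unadjusted p under 0.05 and 3 lower adjusted over the list alone (camera adjusted p = 2.68e-06, adjusted p = 0.225 with an estimated correlation). The genes *rhy-1* and F22B5.4 differed by -1.19 (adjusted p = 0.147) and -1.15 (adjusted p = 0.190). Neuron markers had a median of 0.13 with 25 of 28 positive (camera adjusted p = 0.00262, adjusted p = 0.333 with an estimated correlation), and pharynx markers one of 0.08 (camera adjusted p = 0.0242, adjusted p = 0.590 with an estimated correlation; lost without 20 uM B or 500 uM C at up to 0.205). Endoplasmic reticulum stress genes (median -0.07, camera adjusted p = 0.00639, adjusted p = 0.263 with an estimated correlation; lost without 500 uM C at 0.0560), ribosomal protein genes (median -0.02, camera adjusted p = 0.0202, adjusted p = 0.525 with an estimated correlation; lost without 20 uM C, 500 uM B or 500 uM C at up to 0.235) and muscle markers (median -0.06, camera adjusted p = 0.0325, adjusted p = 0.353 with an estimated correlation; lost without 20 uM A, 500 uM B or 500 uM C at up to 0.151) passed camera as well. In limma 0 members of these 5 lists passed; at an unadjusted p under 0.05 the neuron, pharynx, stress, ribosomal and muscle lists had 2, 4, 2, 0 and 0, and adjusted over the list alone 1 pharynx marker was higher and 1 stress gene lower. The ribosomal and muscle calls were lost under quantile normalization. Without 1 array the pharynx median ran from 0.03 (20 uM B) to 0.18 (20 uM A). The stress median ran from -0.15 (500 uM A) to -0.04 (500 uM C) and the ribosomal median from -0.03 (20 uM B) to -0.01 (20 uM C). The muscle median was -0.03 without 500 uM A.

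In all, 41 of 16911 probe sets differed between 500 and 20 uM hemin by limma, 26 higher and 15 lower, standing for 33 named genes. The count was 182 without 4 uM replicate A, 26 without 4 uM B, 10, 11 and 12 without 20 uM A, B or C, 17 without 500 uM A and 8 without 500 uM B, 203 when only the 6 arrays of these groups entered the fit and 204 with array weights. Over the fits that left out 1 array 0 to 16 lectins and 1 to 4 members of the lysozyme and defence list rose, and 15 lectins rose in the fit of 6 arrays. Without 4 uM A, 16 lectins and 2 pharynx markers rose, and 3 HIF-1 targets, 2 stress genes and 2 heme transport genes fell. Of the 20 genes named for the size of change 4 kept their call in all 9 fits that left out 1 array.

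Both contrasts use the same 20 uM arrays, and the study sorted its genes into 8 categories by the pair of responses. At an adjusted p under 0.05 in each, 110 probe sets were higher at 4 uM alone, 35 lower at 4 uM alone, 22 higher at 500 uM alone and 10 lower at 500 uM alone. The difference between both responses is the contrast of 500 with 4 uM. Lower at both concentrations were 3 probe sets, of *pud-3*, *pud-4* and Y105C5B.7, and higher at both were 3, with F53A9.1 the named gene among them. The genes *hrg-7* and *cpr-8* were higher at 4 uM and lower at 500 uM hemin, and 1 probe set of F09C8.1 went the opposite way (-1.15 and 1.58, and -0.43 without a call and 1.04 for its other probe set). F53A9.1, at 0.58 in both contrasts, and F09C8.1 were chosen for mention after their values were seen. The call of Y105C5B.7 at 4 uM was lost without any 20 uM array and in the fit of 6 arrays (adjusted p up to 0.105). At 500 uM that of *pud-4* was lost without any 20 uM array, 500 uM A or 500 uM B (up to 0.117), that of *hrg-7* without 20 uM B, 20 uM C, 500 uM A or 500 uM B (up to 0.0785), and that of *cpr-8* without 4 uM B, any 20 uM array, 500 uM A or 500 uM B (up to 0.160). In the moderated F-test 274 probe sets differed among the 3 concentrations, and 263 of them also passed in a single contrast.

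**Figure D3:**
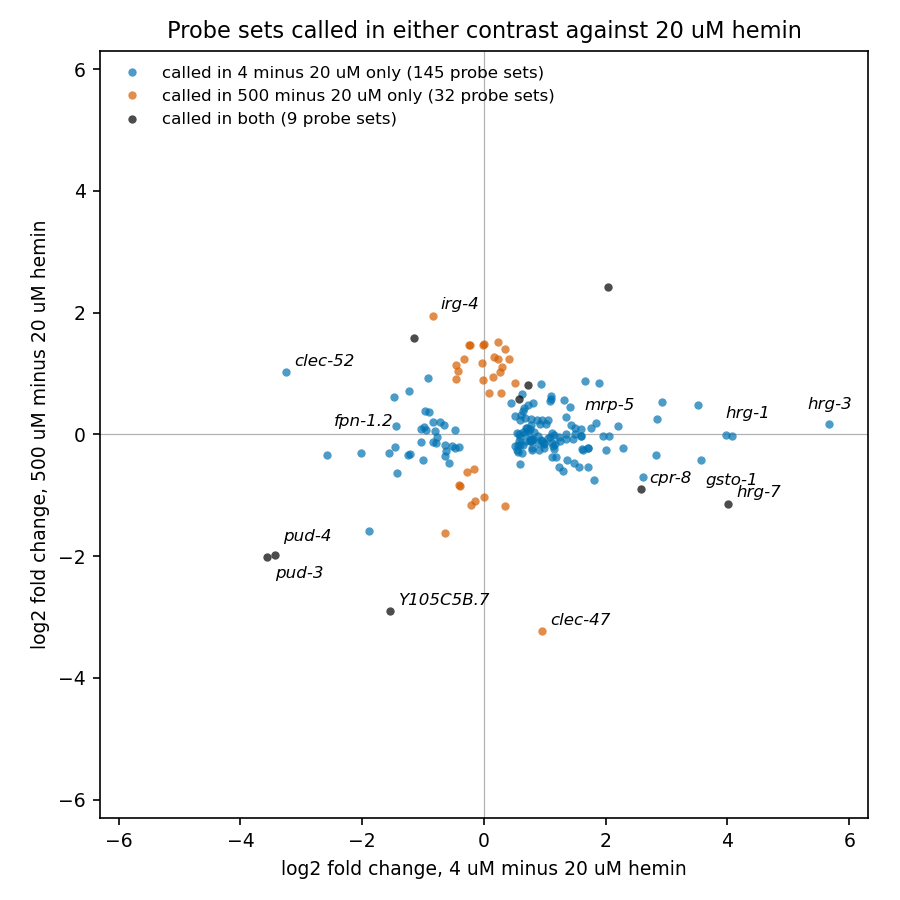
Log2 fold change at 500 uM against 20 uM hemin (y axis) over that at 4 uM against 20 uM hemin (x axis) for 186 probe sets called in either contrast; each point is 1 probe set, coloured by the contrast that called it. The 9 called in both include *hrg-7* and *cpr-8*, higher at 4 uM and lower at 500 uM, and *pud-3* and *pud-4*, lower at both.

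Shared controls alone can produce overlap among top-ranked probe sets. Unchanged groups were simulated 100 times with a simulated control group shared by both contrasts. As many top-ranked probe sets as the real calls (154 and 41) were taken, without an adjusted p. On average 5.37 lay in both lists in the same direction and 0 in opposite directions. Observed were 6 and 3 called probe sets, and independent lists would give 0.211 and 0.162. The simulated overlap is one of ranked lists and not of calls. Every simulated group had the SD that the fit pooled over all 9 arrays. The real 20 uM arrays varied less, with SDs of deviations of 0.15 to 0.18 against 0.21 to 0.43 at 4 uM. The simulation may therefore overstate the overlap that shared controls produce. The correlation of the log2 fold changes across probe sets, which are not independent replicates, was 0.0936 against a simulated 0.497, and the covariance 0.0050 against 0.0111. With 3 arrays the controls could not be split, and part of the same-direction overlap may come from them. The total of 186 probe sets called in either contrast was 448 without 4 uM A, 111 without 4 uM B, 76, 87 and 116 without 20 uM A, B or C, 109 without 500 uM B and 1010 with array weights. The 9 called in both were 49 without 4 uM A, 3, 2 and 2 without 20 uM A, B or C, 4 without 500 uM A, 3 without 500 uM B and 93 with array weights. The F-test count was 507 without 4 uM A, 146 without 4 uM B, 448 without 4 uM C, 172, 176 and 179 without 20 uM A, B or C, 150 without 500 uM B and 1085 with array weights.

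The study's design text counts 375 genes with a 1.6-fold change from 2 processing methods. From the values used here a fold of at least 1.6 without a test took 307 probe sets at 4 uM and 276 at 500 uM, and together with the adjusted p 123 and 37. These are probe sets per contrast and the 375 are genes, so the counts are not alike. By the fold alone 15 probe sets were higher at both concentrations and 20 lower at both. Another 38 were higher at 4 uM and lower at 500 uM, and 10 went the opposite way. How the 375 genes were tested is not given in the sources used here.

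Between 500 and 4 uM hemin, the widest difference in the design, heme transport genes were lower at 500 uM. Of 7 members 5 fell, 6 when adjusted over the list alone, again for a list chosen on these samples: *hrg-3* fell by at least 5.49 (SE 0.31, n = 3 arrays per group, adjusted p = 1.90e-05), a lower bound because of its level at 500 uM, *hrg-7* fell by 5.15 (SE 0.14, adjusted p = 9.75e-08) and *hrg-1* fell by 3.98 (SE 0.11, adjusted p = 9.75e-08). The transcript of *mrp-5* was 2.83-fold lower (SE 0.12 on the log2 scale, adjusted p = 0.000187). The fall of *hrg-4* by 3.29 (SE 0.60, adjusted p = 0.0223) was lost without 4 uM B, 20 uM C or any 500 uM array (up to 0.0992) and in the fit of 6 arrays (0.112). The list's median was -3.29 (camera adjusted p = 6.28e-17, adjusted p = 0.0615 with an estimated correlation). The gene *fpn-1.2* rose by 0.90 (SE 0.10, adjusted p = 0.00137), as 1 of 9 iron homeostasis genes, also adjusted over the list alone.

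All 5 yolk genes fell (median -2.46, 5 adjusted over the list alone, camera adjusted p = 7.83e-10, adjusted p = 0.198 with an estimated correlation), and *vit-2* fell by 3.32 (SE 0.44, adjusted p = 0.00345) and *vit-6* fell by 2.58 (SE 0.38, adjusted p = 0.00711). Of *vit-4* the other probe sets were not called. Of 40 major sperm protein genes 28 fell, 40 adjusted over the list alone (median -1.41, camera adjusted p = 4.24e-39, adjusted p = 0.263 with an estimated correlation), and *msp-76* fell by 1.47 (SE 0.17) and *msp-63* fell by 1.54 (SE 0.22). Of 26 oocyte and embryo genes 11 fell, 22 adjusted over the list alone (median -0.62, camera adjusted p = 7.54e-26, adjusted p = 0.166 with an estimated correlation), and *perm-2* fell by 1.94 (SE 0.16) and the eggshell chondroitin proteoglycan gene *cpg-3* fell by 1.39 (SE 0.15). Without 4 uM replicate A, the array with a sperm list median 0.98 above the other 2, the counts were 5, 26 and 11 and the medians -2.69, -1.13 and -0.54. The 30 genes of germline proliferation and meiosis had a median of -0.09 with 0 passed in limma, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.0248, adjusted p = 0.690 with an estimated correlation; lost without 4 uM A, 4 uM B, 500 uM A or 500 uM C at up to 0.20). Its median was -0.05 without 4 uM A and -0.17 without 4 uM C. Over the 9 fits that left out 1 array 2 to 40 major sperm protein genes, 6 to 17 oocyte and embryo genes and 3 to 5 yolk genes fell, and in the fit of 6 arrays 2, 6 and 3.

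**Figure D4:**
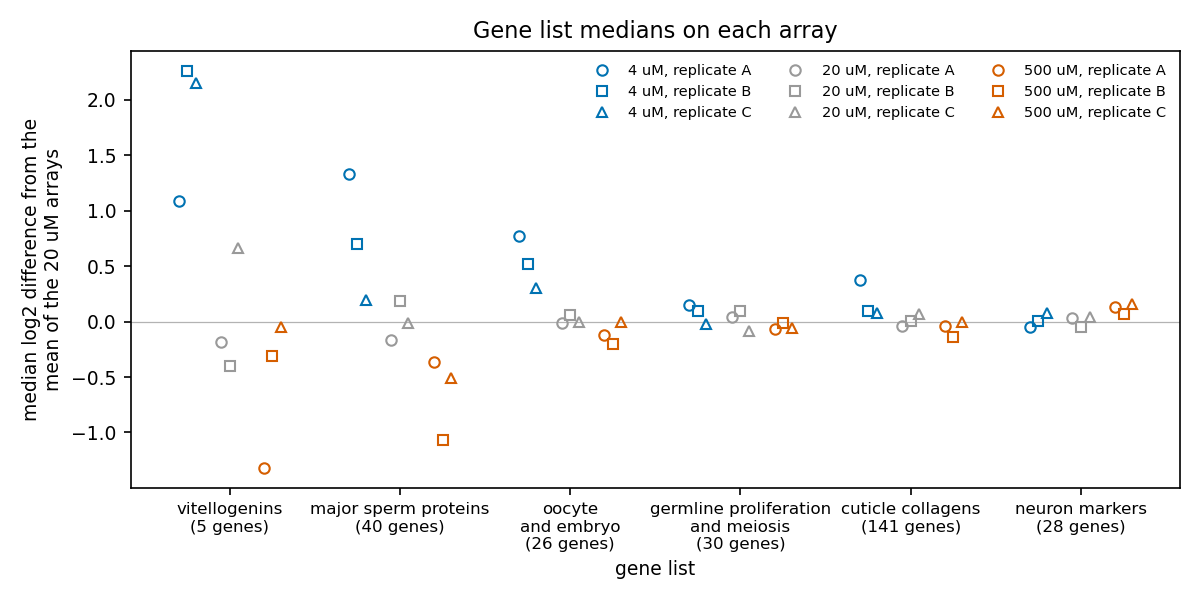
Median over the genes of 6 lists of the log2 difference from the mean of the 20 uM arrays (y axis, log2 units); each point is 1 array, coloured by hemin concentration and shaped by replicate letter. The sperm list median is 1.33 on 4 uM replicate A and -1.07 on 500 uM replicate B.

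Collagens fell in 13 of 141 cases (16 lower and 1 higher adjusted over the list alone; median -0.24, camera adjusted p = 3.02e-15, adjusted p = 0.267 with an estimated correlation; median -0.15 without 4 uM A), and *col-19* fell by 2.50 (SE 0.32, adjusted p = 0.00299) and *col-122* fell by 2.56 (SE 0.33, adjusted p = 0.00282). Histones fell in 4 of 25 cases (8 adjusted over the list alone; median -0.16, camera adjusted p = 1.07e-05, adjusted p = 0.304 with an estimated correlation; median -0.24 without 500 uM B). Over the fits that left out 1 array 7 to 21 collagens and 1 to 4 histones fell, and 0 histones fell in the fit of 6 arrays. Of the 58 members of the lysozyme and defence list 7 rose, 5 of them irg or dod genes and 2 saposin-like (11 higher and 1 lower adjusted over the list alone; median 0.09, camera adjusted p = 0.00400, adjusted p = 0.166 with an estimated correlation), *irg-4* by 2.80 (SE 0.21) and *spp-18* by 1.36 (SE 0.12) among them, 11 without 4 uM A and 4 in the fit of 6 arrays. Among 130 lectins 9 rose and 5 fell (18 and 6 adjusted over the list alone), with *clec-52*, which rose by 4.27 (SE 0.33, adjusted p = 0.000132) and *clec-47*, which fell by 4.18 (SE 0.48, adjusted p = 0.00155). Without 4 uM A camera called lectins (adjusted p = 0.00317). Fatty acid metabolism rose in 4 of 36 cases (4 adjusted over the list alone; median 0.12, camera adjusted p = 0.000667, adjusted p = 0.166 with an estimated correlation). There the lipase gene *lipl-1* rose by 2.08 (SE 0.20, adjusted p = 0.000733) and the desaturase gene *fat-5* by 0.86 (SE 0.10, adjusted p = 0.00187). The enoyl-CoA hydratase gene *ech-9* rose by 1.91 (SE 0.38, adjusted p = 0.0297), a call lost without any of 7 arrays, all but 4 uM C and 500 uM C (up to 0.143), with the replicate block (0.0576) and in the fit of 6 arrays (0.123).

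Peroxidases (median 0.24), pharynx markers (0.21), neuron markers (0.11) and HIF-1 targets (-0.31) passed camera with adjusted p = 0.0320, 0.00639, 0.0326 and 0.0345, and had adjusted p = 0.555, 0.525, 0.481 and 0.503 with an estimated correlation. In limma 0 members of each passed, 1, 2, 4 and 3 had an unadjusted p under 0.05, and 2 HIF-1 targets were lower adjusted over the list alone. Each of these calls was lost without 4 uM A, that of peroxidases also without a filter and with the mean of all probe sets, and that of neuron markers under quantile normalization. The same held without 500 uM B or C for peroxidases (up to 0.502), 500 uM C for pharynx markers (up to 0.492), 500 uM A or C for neuron markers (up to 0.391), and 4 uM C, 500 uM A or 500 uM C for HIF-1 targets (up to 0.242). On 4 uM A the medians of these lists deviated by -0.43, -0.34, -0.11 and 0.82. Without it the first 3 medians were 0.09, 0.09 and 0.05. Without 4 uM C the peroxidase median was 0.42. Without 4 uM A camera called UDP-glucuronosyltransferases (adjusted p = 6.96e-05), mitochondrial stress genes (0.0172) and intestine markers (0.0387) lower and endoplasmic reticulum stress genes (0.0147) higher.

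In all, 350 of 16911 probe sets differed between 500 and 4 uM hemin by limma, 130 higher and 220 lower, for 291 named genes. The count was 168 without 4 uM B, 682 without 4 uM C, 221 without 20 uM C and 227, 175 and 197 without 500 uM A, B or C, 159 when only the 6 arrays of these groups were fitted and 813 with array weights. Of the 20 genes named for the size of change, 17 kept their call in all 9 fits that left out 1 array. Over the 3 contrasts camera called 38 of 108 list tests with the preset correlation and 0 with an estimated one, where 18 had an unadjusted p under 0.05, and fry called 13. Among 99 other groupings of the 9 arrays the median was 21 camera calls and the highest 39.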

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

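The tests of degraded RNA and of the normalization were chosen after the array of 4 uM replicate A was seen to stand apart, and the test of single probe sets was set before its result was seen. A control probe set for the 3' end of the yeast URA3 transcript, outside the measured worm genes, read 4.06 on 4 uM replicate A, against 2.76 to 2.94 on the 20 uM arrays. It was the only one of 77 control probe sets that lay over 1 log2 unit above all 20 uM arrays on some array outside that group.

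The array of 4 uM replicate A lay apart from the other 8. Degraded RNA would raise the 3' over the 5' signal of the worm control transcripts on that array, and it was highest there for 1 of 4 (actin), which argues against it. For GAPDH (0.30), ubiquitin (3.48) and catalase (2.17) the log2 difference was highest on 20 uM replicate A. On 500 uM replicate B it was the lowest for all 4. A difference in RNA quality between those 2 arrays therefore stays open. After quantile normalization the SD of the deviations of 4 uM replicate A was 0.434, against 0.431 as deposited, and still 1.92 times that of 500 uM replicate B. These values argue against a difference in the overall distribution of values as the source. Quartiles were nearly equal beforehand, so the step could change little. It does not test other faults of the authors' normalization or summarisation. A fault of single probe sets stays open: the deviations of paired probe sets of 1 gene correlated with r = 0.352 across 2512 pairs, which are not independent replicates, within the 0.03 to 0.53 of the other arrays. The SD of the difference between the paired deviations was 0.44 on that array, the highest, against 0.14 to 0.29 on the others. A biological difference of that culture, whose sperm and HIF-1 target lists lay 0.98 and 0.82 above the other 2 cultures of its group, may also account for the array's position apart. No test separated such a difference from handling of the sample. In the sperm list the spread was not confined to 1 culture, since 4 uM replicate C deviated by -0.87. The sperm medians against the 20 uM mean were 1.33, 0.70 and 0.19 on 4 uM A, B and C.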

How the results depend on the processing

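All alternatives here were planned, and no gene or list called in limma or camera reversed the direction of its test under any of them. Of 176 results of named genes 11 changed sign in some setting, 0 of them called (*abtm-1* and *hrg-1* at 500 minus 20 among them). The medians of 22 of the 38 called lists moved by over 1.5 times without some array, 10 of them without 4 uM replicate A, and 1 changed sign, that of the lysozyme and defence list at 4 minus 20. The median shift of all fold changes stayed under 0.03 in every scaling. Counts of differing probe sets stayed within 1.5 times under quantile normalization (127, 41 and 362 for 4 minus 20, 500 minus 20 and 500 minus 4 uM hemin), centring, both other filters, both other variance priors, 1 probe set per gene and the fold threshold added to the adjusted p. With array weights, which gave 4 uM replicate A a weight of 0.148, the counts were 899, 204 and 813, the F-test count 1085, and 1010 and 93 probe sets were called in either or in both contrasts with 20 uM. All 154, 41 and 350 probe sets called with equal weights were among these. The weight was 3.93 on 4 uM B and 0.88 on 4 uM C, so the weighted 4 uM mean rested mainly on 1 array. At 20 and 500 uM the weights ran from 0.67 (500 uM B) to 2.55 (20 uM C). The cause of the larger counts was not tested. In fits of only the 6 arrays of a contrast the counts were 86, 203 and 159, so that 500 minus 20 exceeded 4 minus 20, and the arrays of the third group no longer entered the estimate of spread. A fold of at least 1.6 alone took 307, 276 and 571, since it sets no limit on error. Leaving out 1 array at a time gave 69 to 315, 8 to 182 and 168 to 682 probe sets, 146 to 507 in the F-test, 76 to 448 called in either contrast and 2 to 49 in both, and 27 to 41 list calls. Of 38 list calls 24 held without each of the 9 arrays. Camera with an estimated correlation called 0 lists (18 at an unadjusted p under 0.05) and fry 13, of which 12 were among the 38. Fry asks another question. Camera with an estimated correlation asks that of the main test, with the correlation taken from the arrays. The estimates were 0.88 for sperm, 0.77 for yolk, 0.39 for oocyte and 0.17 for collagen genes, against the preset 0.01. For fatty acid metabolism the estimate was 0.0153, and its calls were lost too. Camera's unadjusted p also rose where the estimate lay below the preset. For the lysozyme and defence list at 500 minus 4 (estimate 0.0049) it went from 0.00089 to 0.0103. For heat shock genes at 4 minus 20 (estimate -0.0792) it went from 0.0124 to 0.0413. The size of the correlation therefore does not account for all of the losses. The cause of the losses was not tested further. With the replicate letter as a block the counts were 148, 31 and 321, the F-test gave 236, 168 and 11 probe sets were called in either or both, and the lists gave 38 calls. Of the 154, 41 and 350 probe sets of the main fit 118, 28 and 294 were among these. The letters were not taken to pair the samples, and correlations of deviations between arrays of 1 letter ran from -0.15 to 0.29. A processing step shared by letter is not excluded. Poly-A spike-in means (12 probe sets) were higher on A than on B at each concentration. At 4, 20 and 500 uM they were 9.70, 9.95 and 9.81 on A and 9.40, 8.92 and 8.65 on B. On C they were 9.37, 9.17 and 10.03. For named genes, 1274 results stayed on their side of the threshold when 1 array was left out, 306 lost their call and 4 gained one. Of the 176 results 42 lost their call in the fits of 6 arrays, 22 with the replicate block, 10 under quantile normalization, 6 with centring, 3 without the variance trend and 1 with the robust prior, and of 182 without a filter 7 did. Of 56 counts of list members that passed in one direction 47 moved by over 1.5 times in some setting, array weights among them, and 25 were 0 in some setting. Of the results under another probe set of the gene 23 stayed and 7 lost their call. A pseudocount alternative was not run, because the values were already log2. Signal over background could not be judged without detection calls, and the precision is limited by 3 arrays per group: a log2 change of 0.5 was recovered in 30% of simulated cases for 500 minus 20.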

Other observations

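Tests of 4 uM replicate A alone, of a larger germline and of a later stage were chosen after the results were seen, and those with the oocyte covariate and of other groupings before. Of the 36 lists 15 had no camera call in any contrast, of which UDP-glucuronosyltransferases, intestine markers, copper and iron-sulfur proteins and mitochondrial stress genes gained one without 4 uM A. Among 24 antioxidant enzymes the peroxisomal catalase gene *ctl-2* fell by 0.95 (SE 0.14, limma adjusted p = 0.0124, 1 of 24, also adjusted over the list alone) at 4 against 20 uM hemin, a call lost without 4 uM B, 20 uM A or 20 uM B (up to 0.0770) and in the fit of 6 arrays (0.0699). It rose by 1.02 (adjusted p = 0.00501) at 500 against 4 uM, and at 500 against 20 uM 0 members passed in limma and 0 had an unadjusted p under 0.05. Of 53 UDP-glucuronosyltransferases 1 rose and 1 fell at 500 against 20 uM (3 and 4 adjusted over the list alone), *ugt-18* by 1.17 (adjusted p = 0.0307, lost without 4 uM B, any 20 uM array, 500 uM A or 500 uM B at up to 0.179, under quantile normalization and with the replicate block). The 1 that fell, *ugt-32*, lost its call without 4 uM B, any 20 uM array, 500 uM A or 500 uM B (up to 0.150) and with the replicate block (0.0653). At 500 against 4 uM 4 rose and 4 fell (6 and 11 adjusted over the list alone; 1 to 4 and 1 to 11 without 1 array), and *ugt-17* fell by 1.65 (adjusted p = 0.000219). Of 46 cytochromes P450 1 rose at 4 against 20 uM, *cyp-33C9* by 1.35 (adjusted p = 0.00189), 0 passed in limma at 500 against 20 uM (6 unadjusted), and 1 rose and 2 fell at 500 against 4 uM (0 to 2 and 1 to 3 without 1 array), with 1, 0 and 4 passed adjusted over the list alone.

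Among 50 ABC transporters *mrp-5* was the 1 that rose at 4 against 20 uM, and the P-glycoprotein gene *pgp-1* the 1 that rose at 500 against 20 uM (0.88, adjusted p = 0.0132, with 1 and 3 higher in these contrasts adjusted over the list alone, lost without any 20 uM array, 500 uM A or 500 uM B at up to 0.0951). At 500 against 4 uM 3 rose and 1 fell (4 and 2 adjusted over the list alone; 1 to 3 and 1 to 2 without 1 array). Of 13 genes of the metal and cadmium response the metallothionein gene *mtl-1* rose by 1.01 at 500 against 4 uM (adjusted p = 0.0177, 1 of 13, also adjusted over the list alone, lost without 500 uM B or 500 uM C at up to 0.0698 and in the fit of 6 arrays at 0.0907). In the other contrasts 0 passed in limma, with 4 and 2 at an unadjusted p under 0.05, and 1 lower and 0 adjusted over the list alone. Of 23 genes of lipid binding and lysosomal proteases 2 rose and 2 fell at 4 against 20 uM (4 and 2 adjusted over the list alone; 1 to 3 and 0 to 2 without 1 array), among them the lipid binding protein gene *lbp-3*, which rose by 1.35 (adjusted p = 0.00667, lost at 0.0541 in the fit of 6 arrays). At 500 against 20 uM 1 rose, and at 500 against 4 uM 2 rose and 2 fell, and *lbp-3* fell by 1.42 (adjusted p = 0.00293), with 1 higher, and 4 higher and 2 lower, adjusted over the list alone. The 1 at 500 against 20 uM, *cpr-3*, lost its call without any 20 uM array, 500 uM A or 500 uM B (up to 0.153). Of the 2 at 500 against 4 uM *cpr-3* lost it without 4 uM A, 20 uM C, 500 uM A or 500 uM B and in the fit of 6 arrays (up to 0.134), and *asp-3* without 7 arrays, all but 4 uM A and 4 uM C (up to 0.152), and in the fit of 6 arrays, with centring, with no filter, without the variance trend and with the replicate block. Of 19 intestine markers 1 rose and 1 fell (0 to 2 and 0 to 1 without 1 array), 0 passed and 2 fell in the contrasts in that order, the yolk genes *vit-2* and *vit-6* being members. Adjusted over the list alone these were 2 higher and 1 lower, 0, and 1 higher and 2 lower, with 3 at an unadjusted p under 0.05 where limma passed 0. Of 5 genes of copper and iron-sulfur proteins the copper chaperone gene *cuc-1* rose by 0.69 at 4 against 20 uM (adjusted p = 0.0425), a call lost without 7 arrays, all but 4 uM A and 500 uM B (up to 0.177), under quantile normalization, with centring and in the fit of 6 arrays. In the other contrasts 0 of these 5 passed in limma, 0 and 1 had an unadjusted p under 0.05, and adjusted over the list alone 1 rose at 4 against 20 uM and 1 was lower at 500 against 4 uM. In limma 0 members passed in any contrast among 41 respiratory chain genes, 21 globins, 9 mitochondrial stress genes, 15 hypodermis markers, 7 male-enriched markers and 18 genes of insulin and dauer signalling, and 0 adjusted over the list alone. At an unadjusted p under 0.05 over the 3 contrasts these had 0, 0 and 0, 0, 0 and 0, 0, 0 and 1, 2, 1 and 0, 3, 1 and 0, and 0, 0 and 5 members.

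Oocyte, yolk and sperm genes lay lower at 500 than at 4 uM hemin. The array of 4 uM replicate A alone is argued against, since without it the smallest ratio of the 3 list medians was 0.804, with 0.862 for oocyte and 1.09 for yolk genes. A larger germline as a whole is argued against by the germline proliferation and meiosis list, whose median was -0.0945 with quartiles of -0.17 and -0.02, above the -0.31 that would be 0.5 of the oocyte median. A later stage at harvest at 4 uM hemin stays open as a hypothesis, since the adult collagen gene *col-19* differed by -2.50 between 500 and 4 uM, in line with it, and by -0.22 (adjusted p = 0.979) between 500 and 20 uM. An effect of hemin itself on these genes also stays open, and it was not separated from stage here.

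The genes *hrg-1*, *hrg-3*, *hrg-7* and *mrp-5* were higher at 4 than at 20 uM hemin. Without 4 uM replicate A, 4 of 4 kept their call. With the median of the oocyte and embryo list on each array as a covariate, 4 of 4 kept at least 0.5 of their change, with log2 differences from 1.90 for *mrp-5* to 8.08 for *hrg-3*, which lay near the lowest values at 20 uM, and adjusted p of 0.0025 to 0.0249. The covariate separates the groups fully, however, at 7.81 to 8.14 on the 4 uM arrays and 7.06 to 7.24 on the other 6, so these changes are extrapolated with no overlap. A stage difference that goes with the oocyte genes therefore stays open. A response to low heme is the biological hypothesis that the design names, and it was found and tested on the same arrays.

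Other groupings of the arrays were fitted in the same way. For each single contrast the 6 arrays make 10 splits, too few for a share under 0.05; the counts were 154, 41 and 350 in the real split, 1 of 10 each, and the highest of the others was 0. Of 100 splits of the 9 arrays, 1 gave as many probe sets in the F-test as the real 274 (highest other 114). Likewise 1 gave as many called in either contrast as the real 186 (highest other 152). It was the real split in each case. That is the lowest share 100 splits can give, so chance is not excluded. Both highest others kept the arrays of 4 uM together, so these counts mainly reflect that group and do not test 20 against 500 uM. The count in either contrast also depends on which group serves as the shared control. That group was drawn at random in the other splits, and the real grouping entered only with 20 uM in that place. With 4 uM there it would hold at least the 350 of 500 minus 4. The rank of the 186 is therefore not one among like counts, and no conclusion is drawn from it. For the lists 3 of 100 splits gave at least the real 38 calls, with a highest other of 39. That share is under 0.05, but the median of the other splits was 21 calls. Other splits can keep part of the differences between concentrations. Their calls may come from these, from other structure among the arrays or from correlated genes that the preset correlation leaves out. The splits do not tell these apart. The poly-A spike-in controls, 12 probe sets, averaged 8.65 on 500 uM replicate B to 10.03 on 500 uM replicate C.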
